A study of Populus alba x Populus glandulosa with 18 samples.

How the data were processed

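RNA from roots of 84K poplar, a clone of the hybrid Populus alba x Populus glandulosa, was sequenced in 18 libraries. Per the labels' protocols, total RNA was taken with the RNAprep Pure Plant Kit and libraries were made with a NEBNext Ultra RNA kit for Illumina. The labels give 6 groups of 3 libraries. These are the wild type (WT), 1 knockout line of bHLH58 (bhlh58-KO, line 6), 1 of bHLH151 (bhlh151-KO, line 40), 1 of both genes (bhlh58/151-KO, line 32), and 1 overexpression line of each gene (bHLH58-OE, line 20, and bHLH151-OE, line 17). The labels do not say whether the 3 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which can be technical. Each genotype is 1 line, so a genotype and its line are the same samples.

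The deposited table holds 1 value per gene ID and library in FPKM (fragments scaled by transcript length and by the mapped fragments of the library), the unit the deposited table's name gives and its values do not contradict. It has 71159 IDs, of which 11279 are at 0 in every library. The submitters' processing notes name DESeq2, with no version and no role. The aligner, the program that made the FPKM values, the genome build, the annotation and any filter are not given in the sources used here. The IDs are of the forms PAxG, with a number and the letter A or G, and NewGene. The files do not pair them with gene names, and no annotation or genome was used here. The 35 gene lists fixed before the data were examined, which included the markers of other cell types, matched 0 IDs, so no list was tested. The IDs of bHLH58 and bHLH151 are likewise not identified in the sources used here, so the knockout and overexpression labels were not checked on the targeted genes. No coordinates are given for the same reason.

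FPKM is not a count, so no count test was run. Library depth is unknown. A search for whole-read steps compared IDs under 0.3 FPKM in all 153 pairs of libraries. At least 3213 IDs entered each pair, and the fullest bin of 0.02 on the log2 scale held at most 1.58% of their ratios, so no depth could be recovered. FPKM totals ran from 514745 to 536562 per library, and they say nothing of depth.

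Values were transformed as log2(FPKM + 1). IDs with at least 1 FPKM in at least 3 of the 18 libraries were tested, which left 40951 IDs with at least 99.3% of each library's total FPKM. All libraries entered 1 limma fit (limma 3.58.1, R 4.3.3; lmFit, contrasts.fit and eBayes with trend and robust estimation) with a mean per group and 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and 10 comparisons were made. They were the 5 transgenic lines against WT, the double knockout against each single knockout, each overexpression line against the knockout of the same gene, and the non-additive contrast of the double knockout. That contrast is the double knockout minus both single knockouts plus WT. Every log2 fold change is on the log2(FPKM + 1) scale, which understates changes of low genes. An exact 0 in FPKM can be a failed estimate, so an ID at 0 in a whole group is given per library, without a fold change against that group.

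On simulated data with the spread of the real fit and 40951 genes, the same procedure recovered 67 of 67 simulated 2-fold changes for bhlh58-KO against WT, 64 of 67 for bhlh151-KO, 60 of 67 for bhlh58/151-KO, 61 of 67 for bHLH58-OE and 65 of 67 for bHLH151-OE. Of 67 simulated 1.5-fold changes it recovered 46, 42, 47, 40 and 41 in the same order. The changes were shifts on the log2(FPKM + 1) scale, in IDs with a WT mean of at least 1 on that scale. Recovery of lower IDs is therefore not covered. All lines had the same simulated spread, so differences between them reflect the IDs drawn and the random noise.

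Comparisons against WT share 3 libraries, so overlaps of calls are given beside 2 values. One is the mean of 20 simulations of unchanged groups that share simulated WT libraries, and the other is the overlap of independent lists. Effect SDs and corrected correlations are computed over genes after subtracting the sampling variance and covariance estimated from the replicates, and genes are not independent replicates. Their errors are jackknife standard errors over libraries.

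Without gene names, the rule for named IDs took at most 2 IDs that rose and 2 that fell per comparison. These were the largest log2 fold changes among called IDs with a change of at least 2-fold, all libraries of a group outside the range of the other (not asked of the non-additive contrast), and a mean of at least 5 FPKM in the higher group. A further part of the rule, on IDs moved in opposite directions by overexpression and knockout, was left out to keep to that number, after its values had been seen. IDs named in the closing section outside the rule were chosen after their values were seen, and this is said there.

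The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, a fit of only the compared groups, limma without trend and robust estimation, a replicate block, a 2-fold threshold, library weights, and leaving out each library in turn. Leave-one-out fits keep the other groups. No 2 libraries had identical values.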

Results

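Root transcriptomes of 84K poplar were measured in 18 RNA-seq libraries, with 3 each from wild type (WT), bhlh58-KO, bhlh151-KO, bhlh58/151-KO, bHLH58-OE and bHLH151-OE plants. The names bHLH58 and bHLH151 stand for basic helix-loop-helix proteins, a family of transcription factors. The series set out to find genes that act before or after these factors in connection with a root phenotype. Values are FPKM, given as mean ± SD with n = 3 libraries per group unless each library is listed. Genes appear by the IDs of the deposited table, which are not paired with gene names in the sources used here. The 2 targeted genes were for that reason not examined. Library depth is unknown, and the number of IDs with at least 1 FPKM ran from 36450 to 38499 per library.

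Libraries of a group lay close together. Pearson correlations of log2 values over genes ran from 0.981 to 0.987 within groups and from 0.918 to 0.978 between groups. The first principal component held 40.7% of the variance and ordered the groups from WT (-44.5 ± 1.99) through bHLH58-OE (-33.1 ± 1.16), bhlh58-KO (-11.9 ± 1.98), bhlh58/151-KO (6.36 ± 3.04) and bHLH151-OE (18.4 ± 3.64) to bhlh151-KO (64.9 ± 0.398). The double knockout thus lay between both single knockouts on this axis. The second component, with 12.2% of the variance, separated bhlh58-KO (30.5 ± 1.65) and bhlh58/151-KO (20.5 ± 3.58) from WT (-22.1 ± 1.07) and bHLH151-OE (-19.9 ± 5.44).

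**Figure D1:**
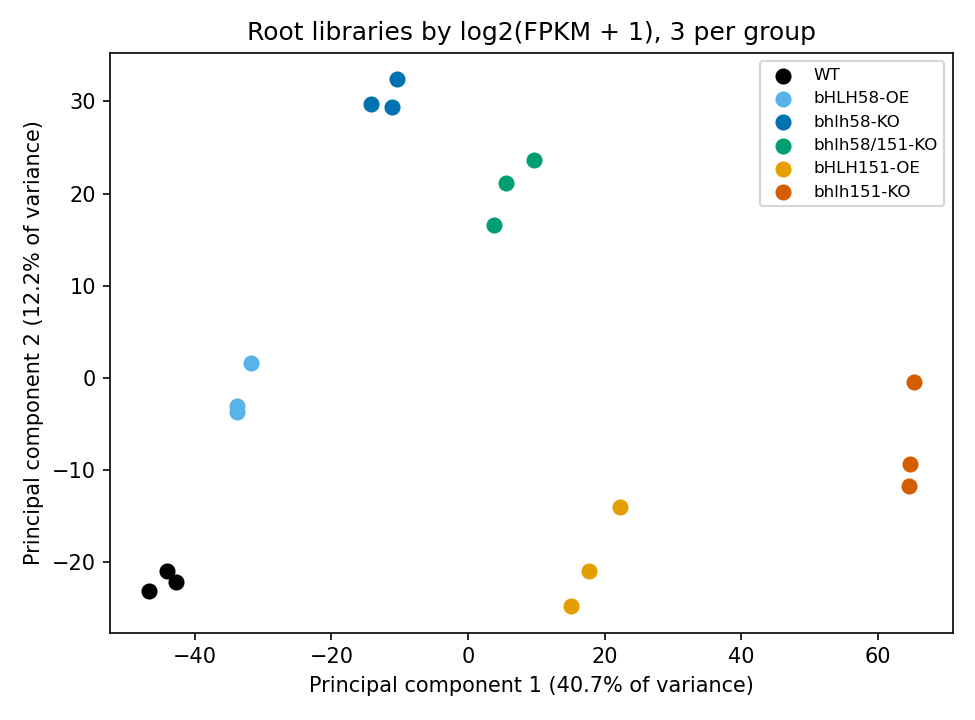
Scores of the 18 root libraries on the first (horizontal, 40.7% of variance) and second (vertical, 12.2%) principal component of log2(FPKM + 1) over 40951 IDs. Each point is 1 library, colored by group, and the 3 libraries of each group form a separate cluster, with WT at one end of the first axis and bhlh151-KO at the other.

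Loss of bHLH58 was examined in bhlh58-KO against WT. PAxG06Gg0057900 rose from 5.11 ± 2.58 to 64.3 ± 28.0 FPKM (log2 fold change 3.42, SE 0.44, limma adjusted p = 0.000115), and PAxG06Ag0058500 rose from 3.57 ± 1.36 to 44.6 ± 19.7 (3.28, SE 0.33, limma adjusted p = 9.71e-06). PAxG13Ag0088600 fell from 90.5 ± 14.5 to 6.17 ± 1.15 FPKM (-3.68, SE 0.15, limma adjusted p = 3.47e-11). PAxG11Gg0025800 fell from 6.72 ± 1.16 to 0.0097 ± 0.017 (-2.92, SE 0.13, limma adjusted p = 3.02e-11). In all, 9158 of 40951 tested genes were called, 5264 higher and 3894 (42.5%) lower in the knockout, with 43.7% lower under median-of-ratios scaling, 47.5% after rescaling to TPM and 49.6% under quantile normalization. Most changes were small, and 311 higher and 197 lower genes changed at least 2-fold.

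Loss of bHLH151 was accompanied by the largest number of calls among the 5 lines, 19828 genes. NewGene_1461 rose from 1.54 ± 0.567 FPKM in WT to 47.4 ± 0.907 in bhlh151-KO (log2 fold change 4.28, SE 0.12, limma adjusted p = 2.98e-15). PAxG05Ag0135100 fell from 36.6 ± 2.17 to 0.184 ± 0.213 (-5.0, SE 0.092, limma adjusted p = 1.99e-17), and PAxG17Gg0168600 fell from 75.6 ± 1.07 to 3.87 ± 0.40 (-3.98, SE 0.091, limma adjusted p = 2.32e-16). PAxG03Gg0128300 was listed at 0 in the 3 WT libraries and at 25.2, 52.1 and 91.2 FPKM in those of bhlh151-KO (limma adjusted p = 0.0249). Its values were uneven elsewhere too, with 0, 0 and 82.8 FPKM in the double knockout, and its adjusted p rose above 0.05 when any WT library, bhlh151-KO replicate 2 or bhlh151-KO replicate 3 was left out (0.0563 to 0.0734). At 2-fold or more, 1504 genes were higher and 1540 lower. Of all calls, 7209 were higher and 12619 (63.6%) lower. That split differed between scalings: 47.5% were lower under median-of-ratios scaling, 52.4% under quantile normalization and 66.5% after rescaling to TPM, and the median log2 fold change of all genes was -0.11 as deposited and -0.005 under median-of-ratios scaling.

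Loss of both factors was examined in bhlh58/151-KO against WT. The 2 IDs with the largest rises were those named for bhlh58-KO. PAxG06Ag0058500 reached 55.9 ± 15.8 FPKM (log2 fold change 3.64, SE 0.33, limma adjusted p = 2.55e-06) and PAxG06Gg0057900 reached 70.6 ± 21.9 (3.59, SE 0.44, limma adjusted p = 5.55e-05). In the same order, they also rose in bhlh151-KO (3.70 and 3.62, limma adjusted p = 4.03e-07 and 1.56e-05). Both rose in bHLH151-OE as well (2.22 and 2.20, limma adjusted p = 0.000152 and 0.00196). Neither was called in bHLH58-OE (limma adjusted p = 0.409 and 0.865). Their rise was thus not particular to loss of bHLH58. PAxG11Ag0028900 fell from 20.5 ± 2.58 FPKM in WT to 1.60 ± 0.681 in the double knockout (-3.08, SE 0.15, limma adjusted p = 2.42e-10). PAxG03Gg0099500 was at 14.1, 13.1 and 16.4 FPKM in the WT libraries and listed at 0 in the 3 double-knockout libraries (limma adjusted p = 0.0457). It was also listed at 0 in 2 of the 3 libraries of bhlh58-KO, of bhlh151-KO and of bHLH58-OE, and its call ended under median-of-ratios scaling (0.0507), under the replicate block (0.0526) and with any library of the 2 groups left out (0.0912 to 0.101). Of 11814 called genes, 5150 were higher and 6664 (56.4%) lower, while 622 higher and 188 lower genes changed at least 2-fold. The lower share was 42.7% under median-of-ratios scaling, 52.5% under quantile normalization, 64% after rescaling to TPM and 48.5% among genes with a mean of at least 5 FPKM.

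Overexpression of bHLH58 gave the fewest calls, 2199 genes, with 1352 higher and 847 (38.5%) lower, and with 38.8% lower under median-of-ratios scaling, 44.9% under quantile normalization and 43.9% after rescaling to TPM. PAxG10Gg0119200 rose from 0.265 ± 0.0992 FPKM in WT to 6.66 ± 1.13 in bHLH58-OE (log2 fold change 2.59, SE 0.15, limma adjusted p = 1.99e-09), and NewGene_1392 rose from 12.8 ± 1.14 to 76.3 ± 7.58 (2.49, SE 0.099, limma adjusted p = 2.59e-11). NewGene_1392 was above WT in the other lines too, at 92.2 ± 9.58 FPKM in bhlh58-KO, 92.0 ± 10.2 in the double knockout, 68.4 ± 5.62 in bhlh151-KO and 44.0 ± 3.41 in bHLH151-OE. PAxG11Gg0025800 fell from 6.72 ± 1.16 to 0.083 ± 0.021 (-2.82, SE 0.13, limma adjusted p = 5.36e-11) and PAxG19Gg0020500 from 44.2 ± 5.82 to 6.86 ± 3.16 (-2.60, SE 0.22, limma adjusted p = 2.84e-06). At 2-fold or more, 93 genes were higher and 76 lower. The count fell to 1338 without WT replicate 1, 1403 without WT replicate 3, 1423 without bHLH58-OE replicate 1 and 1361 without bHLH58-OE replicate 3.

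Overexpression of bHLH151 gave 13091 calls, 4722 higher and 8369 (63.9%) lower. NewGene_1461, the ID that rose in bhlh151-KO, also rose in bHLH151-OE, to 13.9 ± 1.61 FPKM (log2 fold change 2.57, SE 0.12, limma adjusted p = 2.77e-11). PAxG06Gg0048600 rose from 9.71 ± 1.24 to 60.3 ± 2.16 (2.52, SE 0.11, limma adjusted p = 1.61e-11) and stood at 61.3 ± 1.90 in bhlh151-KO. PAxG17Gg0168600 fell to 9.37 ± 0.703 (-2.89, SE 0.091, limma adjusted p = 4.36e-13), and PAxG18Ag0012800 fell from 28.9 ± 0.907 to 5.03 ± 1.03 (-2.32, SE 0.16, limma adjusted p = 2.78e-09). PAxG18Ag0012800 was below WT in the other lines too, at 3.57 ± 1.06 FPKM in bhlh151-KO, 8.38 ± 0.384 in bhlh58-KO, 8.75 ± 1.98 in the double knockout and 14.5 ± 2.20 in bHLH58-OE. At 2-fold or more, 552 genes were higher and 271 lower. The lower share of all calls was 45% under median-of-ratios scaling, 53.1% under quantile normalization and 68.7% after rescaling to TPM.

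**Figure D2:**
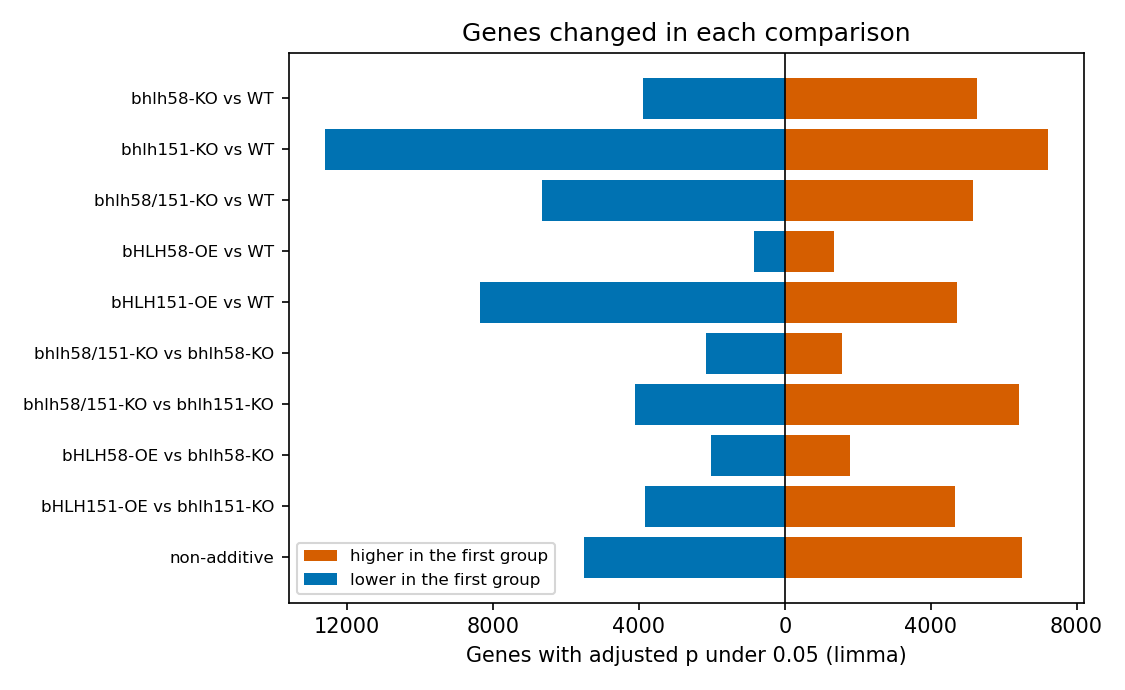
Number of genes with a limma adjusted p under 0.05 in each of the 10 comparisons (horizontal axis), higher in the first-named group to the right and lower to the left. For the non-additive contrast, right and left mean above and below the sum of the single knockouts. The bars are longest for bhlh151-KO against WT (7209 higher, 12619 lower) and shortest for bHLH58-OE against WT (1352 higher, 847 lower). The balance of right and left differs between scalings. The longer side changes under median-of-ratios scaling or quantile normalization in all but bhlh58-KO and bHLH58-OE against WT.

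The knockouts shared many of their calls against WT. The 2 single knockouts had 6477 genes called in the same direction and 424 in opposite directions, where independent lists give 2126.6 and 2307.6. The double knockout shared 6075 same-direction calls with bhlh58-KO (1295.7 for independent lists) and 9273 with bhlh151-KO (2960.1). In simulations of unchanged groups that share simulated WT libraries, the same-direction overlaps were at most 0.05 genes on average. Unchanged groups have almost no calls, so this value cannot show how far shared controls raise the overlap of long lists. The covariance of log2 fold changes was 0.114 for the 2 single knockouts, 0.0916 for bhlh58-KO with the double and 0.147 for bhlh151-KO with the double, beside simulated values of 0.0101, 0.0102 and 0.0101. The 3 WT libraries do not make 2 sets of at least 2 libraries and were not split, so part of the excess in overlap may come from the shared controls. In all 3 knockouts, 2608 genes were higher and 2589 lower.

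Against bhlh58-KO, the double knockout asks what loss of bHLH151 adds where bHLH58 is already lost. PAxG10Ag0208400 rose from 6.73 ± 2.51 FPKM in bhlh58-KO to 32.0 ± 4.36 (log2 fold change 2.13, SE 0.31, limma adjusted p = 0.000586), and NewGene_868 rose from 0.520 ± 0.513 to 5.39 ± 0.682 (2.12, SE 0.18, limma adjusted p = 8.68e-07). PAxG02Gg0066500 fell from 6.20 ± 0.315 to 0.101 ± 0.065 (-2.71, SE 0.14, limma adjusted p = 2.16e-09). PAxG02Ag0067000 fell from 5.84 ± 0.375 to 0.057 ± 0.098 (-2.70, SE 0.15, limma adjusted p = 3.46e-09), and it was listed at 0 in every WT and bHLH151-OE library. The comparison called 3722 genes, 1562 higher and 2160 (58%) lower, with 37.3% lower under median-of-ratios scaling, 50% under quantile normalization and 63.5% after rescaling to TPM. The count fell to 2431 without bhlh58-KO replicate 2 and to 2353 without bhlh58/151-KO replicate 2.

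Against bhlh151-KO, the double knockout asks what loss of bHLH58 adds where bHLH151 is already lost. As in the comparison with bhlh58-KO, the lines are separate, so changes particular to a line enter too. PAxG05Ag0135100, near 0 in bhlh151-KO, was at 27.9 ± 1.93 FPKM in the double knockout (log2 fold change 4.62, SE 0.092, limma adjusted p = 8.71e-17). PAxG05Ag0135300 was at 8.70 ± 0.553 against 0.278 ± 0.196 in bhlh151-KO (2.93, SE 0.11, limma adjusted p = 4.42e-13). In WT these 2 IDs were at 36.6 ± 2.17 and 9.63 ± 0.928. Both were near 0 in line 40 of bhlh151-KO alone, so their difference may belong to that line rather than to loss of bHLH58. NewGene_1461 was lower in the double knockout, at 4.62 ± 0.279 (-3.11, SE 0.12, limma adjusted p = 6.37e-13), as was PAxG07Gg0080800, at 4.29 ± 1.07 against 38.9 ± 2.71 (-2.93, SE 0.13, limma adjusted p = 2.78e-12). In total 10526 genes were called, 6419 higher and 4107 (39%) lower, with 51.6% lower under median-of-ratios scaling, 49.1% under quantile normalization and 40.8% after rescaling to TPM.

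The non-additive contrast asks whether the double knockout departs from the sum of the single-knockout changes. PAxG05Ag0135100 had the largest positive departure, with a log2 interaction of 4.91 (SE 0.13, limma adjusted p = 1.73e-14), and NewGene_1461 the largest negative one (-3.73, SE 0.17, limma adjusted p = 9.71e-12). PAxG05Ag0135100 was near 0 in bhlh151-KO alone, and a change particular to that line would give the same departure. PAxG10Gg0119200 was at 7.15 ± 0.781 FPKM in bhlh58-KO and 3.12 ± 0.488 in bhlh151-KO but 1.01 ± 0.287 in the double knockout (-3.73, SE 0.21, limma adjusted p = 1.16e-10). PAxG01Gg0423000 was at 5.94 ± 1.98 in WT, 2.09 ± 2.93 and 0.263 ± 0.115 in the bhlh58 and bhlh151 knockouts, and 5.37 ± 0.373 in the double (3.88, SE 0.77, limma adjusted p = 0.0017). Its bhlh58-KO libraries were uneven, at 5.48, 0.488 and 0.303 FPKM, and it was not called in bhlh58-KO against WT (limma adjusted p = 0.0595). The contrast called 12003 genes, 6494 above and 5509 (45.9%) below the sum, with 54.4% below under median-of-ratios scaling and 44.6% after rescaling to TPM. In 9893 of them the double-knockout change lay between 0 and the sum of the singles, and in 1993 it had the opposite sign. Over all tested genes the slope of the double-knockout change on that sum was 0.377 (jackknife SE 0.019), where additive changes give a slope of 1. WT libraries that stand apart from all lines would also bring this slope below 1, and that share was not separated.

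**Figure D3:**
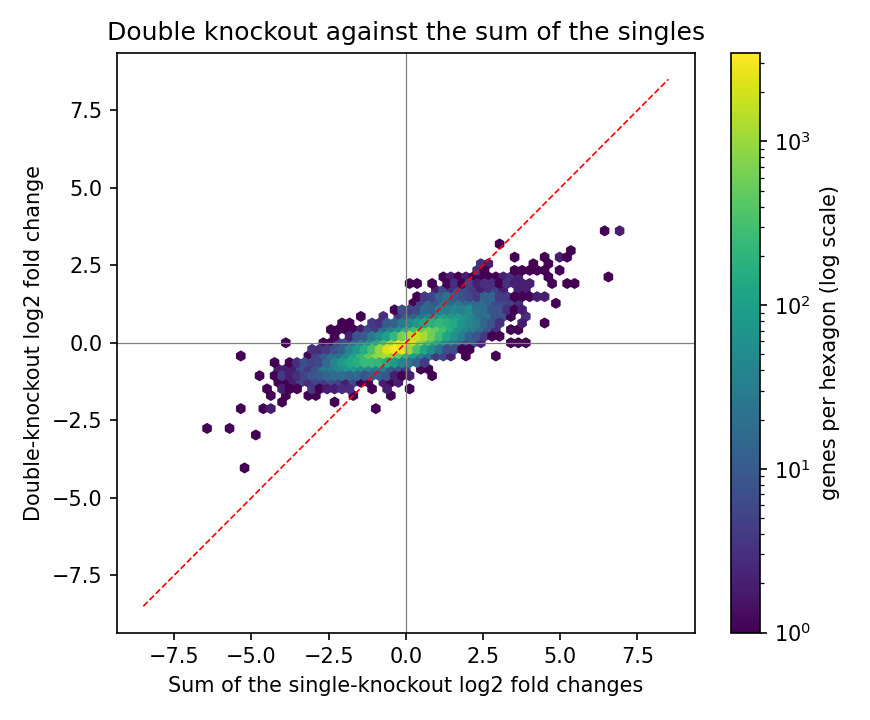
Log2 fold change of each of 40951 genes in the double knockout against WT (vertical) and the sum of its log2 fold changes in both single knockouts (horizontal), with color for the number of genes per hexagon on a log scale. The dashed line marks additive changes, and the cloud is flatter than the line (error-corrected slope 0.377).

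Each overexpression line was set against the knockout of the same gene, and both moved genes mostly in the same direction relative to WT. For bHLH151, 10695 genes were called in the same direction in both lines and 184 in opposite directions, where independent lists give 3410.2 and 2928.4. For bHLH58 the numbers were 1640 and 52, beside 254.3 and 237.4. The covariance of log2 fold changes was 0.164 for bHLH151 and 0.0488 for bHLH58, beside 0.0101 simulated for unchanged groups that share simulated WT libraries. Part of the excess in overlap may come from the shared controls. The changes in the overexpression lines were the smaller ones: the slope on the knockout was 0.551 (jackknife SE 0.029) for bHLH151 and 0.423 (SE 0.032) for bHLH58.

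**Figure D4:**
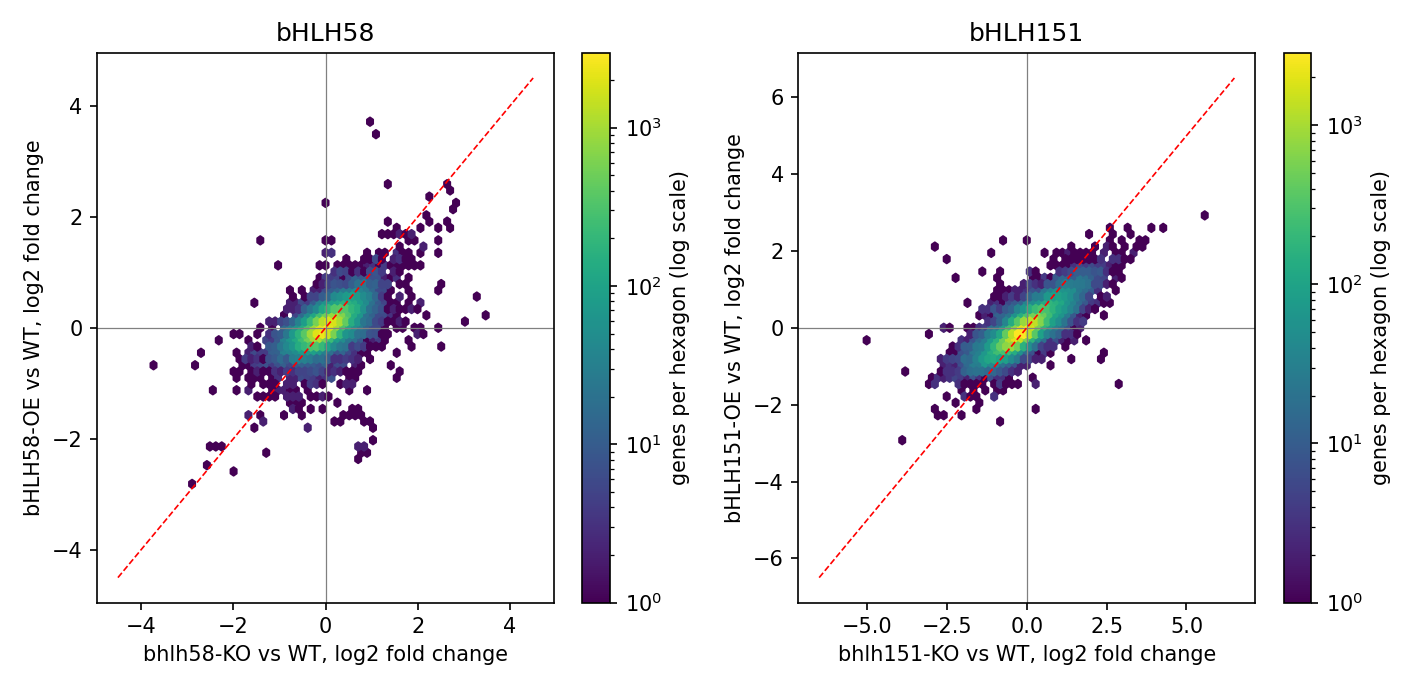
Log2 fold change against WT in the overexpression line (vertical) and in the knockout (horizontal) of bHLH58 (left) and bHLH151 (right), for 40951 genes, with color for the number of genes per hexagon on a log scale. The dashed line marks equal changes, and in both panels the cloud runs from lower left to upper right at a slope flatter than the dashed line (0.423 and 0.551).

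The direct contrast of overexpression and knockout has no WT library in it. PAxG13Ag0088600 was at 55.1 ± 7.42 FPKM in bHLH58-OE and 6.17 ± 1.15 in bhlh58-KO (log2 fold change 2.97, SE 0.15, limma adjusted p = 6.31e-10). Both lines were below WT for this ID, which was at 90.5 ± 14.5 there (bHLH58-OE against WT -0.70, limma adjusted p = 0.0108). PAxG01Ag0006200 was at 1.83 ± 0.343 in bHLH58-OE against 24.4 ± 1.28 in bhlh58-KO (-3.17, SE 0.14, limma adjusted p = 4.37e-11), with WT between them at 12.9 ± 1.67. PAxG06Gg0057900 was lower in bHLH58-OE, at 6.43 ± 3.64 FPKM (-3.22, SE 0.44, limma adjusted p = 0.000552), a call lost in a fit of only these 2 groups (0.05001). PAxG02Ag0040600 was at 5.56, 6.97 and 7.25 FPKM in the bHLH58-OE libraries and listed at 0 in those of bhlh58-KO (limma adjusted p = 0.00647). In this pair of lines 3804 genes were called, 1789 higher and 2015 (53%) lower in the overexpression line, with 52% lower under median-of-ratios scaling, 47.7% under quantile normalization and 51.6% after rescaling to TPM. That count fell to 2498 without bhlh58-KO replicate 3 and to 2371 without bHLH58-OE replicate 3.

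For bHLH151 the contrast called 8512 genes, 4665 higher and 3847 (45.2%) lower in bHLH151-OE, with 52.7% lower under median-of-ratios scaling, 47.8% under quantile normalization and 45.4% after rescaling to TPM. PAxG11Gg0025800 was at 33.6 ± 4.24 FPKM in bHLH151-OE, 6.72 ± 1.16 in WT and 0.066 ± 0.099 in bhlh151-KO (log2 fold change 5.02, SE 0.13, limma adjusted p = 3.01e-15). PAxG05Ag0135100 was at 30.7 ± 0.830 in bHLH151-OE, 36.6 ± 2.17 in WT and 0.184 ± 0.213 in bhlh151-KO (4.76, SE 0.092, limma adjusted p = 5.09e-17). PAxG10Ag0148900 was at 0.369 ± 0.049 against 11.4 ± 0.810 in bhlh151-KO (-3.18, SE 0.12, limma adjusted p = 1.43e-12), and PAxG09Gg0074700 at 1.54 ± 0.619 against 18.5 ± 3.07 (-2.96, SE 0.35, limma adjusted p = 2.06e-05). The 2 overexpression lines shared 1351 same-direction and 94 opposite calls against WT, beside 329.0 and 374.0 for independent lists. Their covariance was 0.0445 beside 0.010 simulated for unchanged groups. The uncorrected correlation was 0.499 beside 0.4996 simulated, a value that sampling error of shared WT libraries gives by itself. Corrected for that error it was 0.524 (jackknife SE 0.035). The corrected value for overexpression with knockout of the same gene was 0.683 (SE 0.055) for bHLH58 and 0.848 (SE 0.030) for bHLH151. WT libraries that stand apart from all lines would also raise these values.

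**Figure D5:**
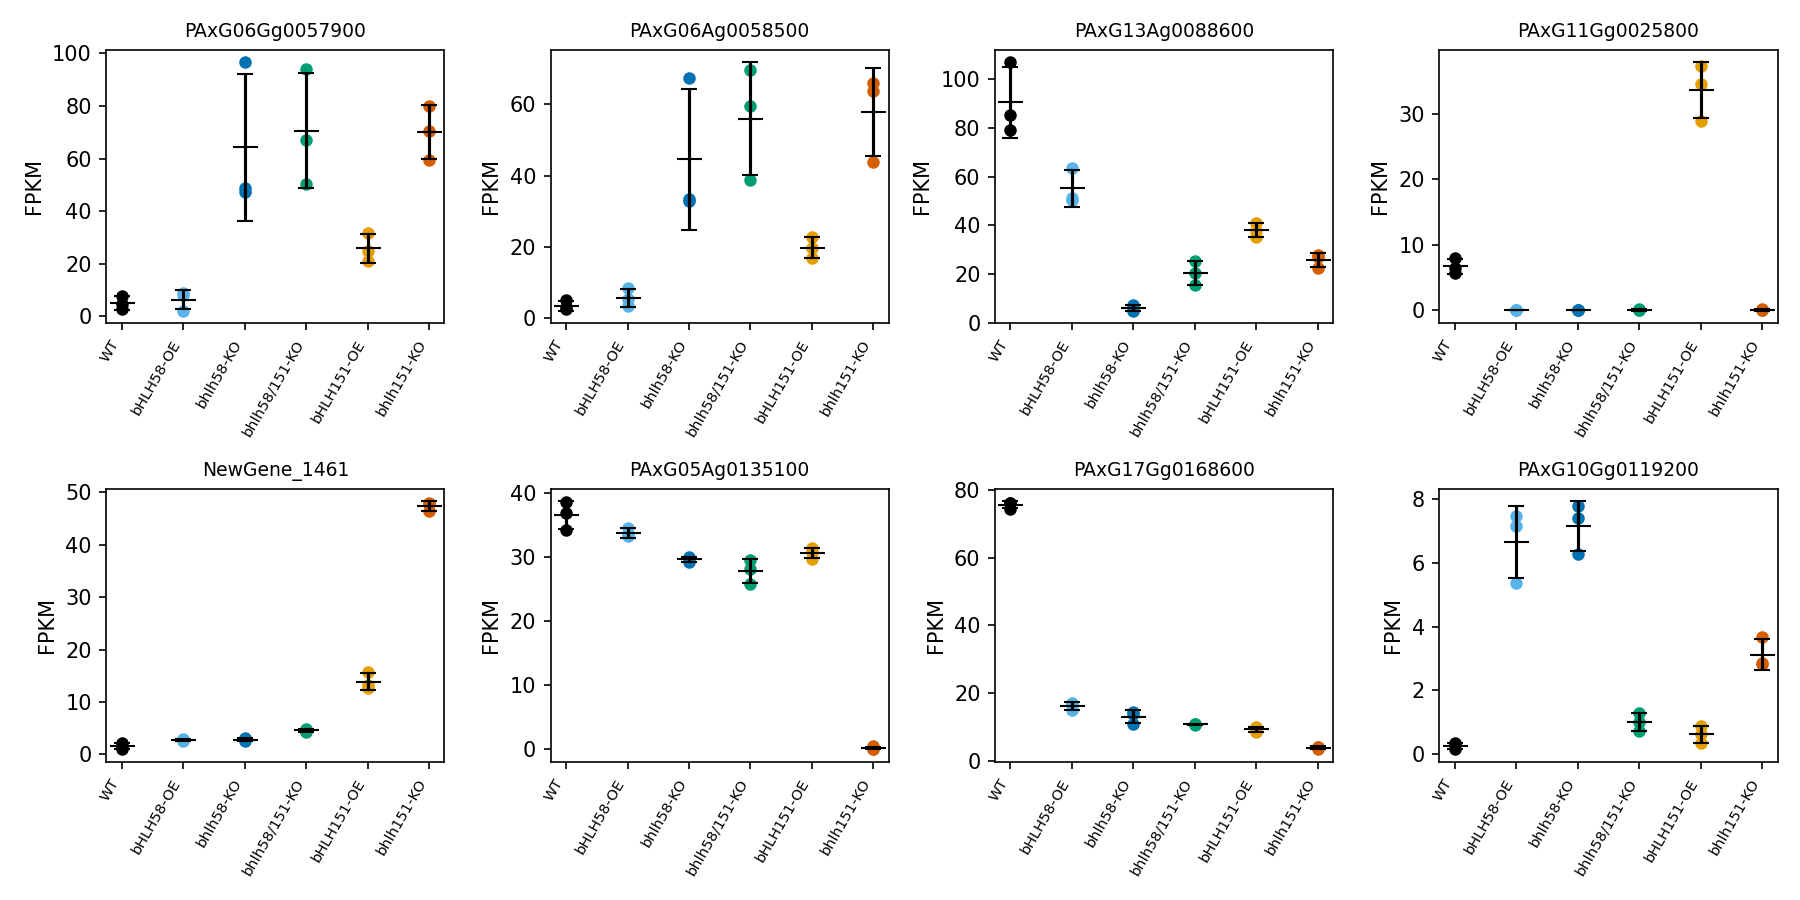
FPKM (vertical) of the 8 IDs that the naming rule picked in more than 1 comparison, in each group (horizontal). Points are libraries, the dash is the mean and the bars are the SD of 3 libraries. PAxG05Ag0135100 is near 0 in bhlh151-KO alone, PAxG11Gg0025800 is above 28 FPKM in bHLH151-OE alone, and PAxG17Gg0168600 is lower than WT in all 5 lines.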

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

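The tests of explanations in this part were chosen after the result they address had been seen; the interaction and the splits of the libraries were planned.

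In 12003 genes the log2 change on losing one factor differed with the state of the other in these lines, by a test of the difference itself (the interaction of the 2 knockouts in limma). WT libraries that stand apart from all lines would also give such a difference. So would a change particular to a line, since each genotype is 1 line, and these sources were not told apart. Over all tested genes, 927 were called in 1 direction against the other 5 groups in WT and 4467 in bhlh151-KO. In 235 of the 12003 genes the sum of the single changes lay below 0 FPKM, a level the double knockout cannot reach, and in 18 of those this floor set over 0.5 of the interaction. In 100 random splits of the 12 libraries of WT and the 3 knockouts, the real split included, 1 gave as many genes, the real one, and the highest of the others gave 9169. These splits also mix the wide differences between the 4 groups, so other splits call many genes. For that reason they do not test the interaction by itself, and nothing is concluded from them. Of the 26 named IDs, 20 had a called interaction. The log2 interaction was 4.91 for PAxG05Ag0135100, 3.88 for PAxG01Gg0423000, 3.74 for PAxG17Gg0168600, 3.32 for PAxG13Ag0088600, 2.97 for PAxG05Ag0135300, 2.94 for PAxG19Gg0020500, 2.77 for PAxG18Ag0012800, 1.78 for PAxG11Ag0028900 and 1.63 for NewGene_868. It was -2.10 for PAxG06Gg0048600, -2.34 for NewGene_1392, -3.28 for PAxG07Gg0080800, -3.34 for PAxG06Ag0058500, -3.42 for PAxG10Ag0148900, -3.45 for PAxG06Gg0057900, -3.56 for PAxG02Gg0066500 and -3.73 for both NewGene_1461 and PAxG10Gg0119200. That of PAxG11Gg0025800, 2.91, was set by the floor for 2.84, since the ID was near 0 in all 3 knockouts, and shows no such difference; the floor set 1.21 of the value for PAxG01Gg0423000, 0.44 for PAxG11Ag0028900, 0.18 for PAxG17Gg0168600 and 0.063 for PAxG05Ag0135100. PAxG02Ag0067000, at 0 in the 3 WT libraries, is given per library: 6.01, 6.10 and 5.41 FPKM in bhlh58-KO, 1.63, 0.670 and 0.860 in bhlh151-KO, and 0, 0.170 and 0 in the double knockout (limma adjusted p of the interaction 1.68e-10).

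For the 9 comparisons of 2 groups, 10 splits of the 6 libraries exist, so no share under 0.1 can be reached. The real split was the 1 with the most genes each time. Every other split mixes libraries of both groups, so differences between the groups widen its spread and lower its count. The counts of the other splits are therefore no measure of false calls. The real and the highest other count were 9158 and 1 for bhlh58-KO against WT, 19828 and 1 for bhlh151-KO, 11814 and 0 for the double knockout, 2199 and 0 for bHLH58-OE and 13091 and 2 for bHLH151-OE. They were 3722 and 1 for the double against bhlh58-KO, 10526 and 0 for the double against bhlh151-KO, 3804 and 0 for bHLH58-OE against bhlh58-KO, and 8512 and 6 for bHLH151-OE against bhlh151-KO.

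Overexpression and knockout of the same gene moved genes the same way. Sampling error of the shared WT libraries gives a covariance of 0.0101, below the observed 0.1642 for bHLH151 and 0.0488 for bHLH58. WT libraries that stand apart from all lines are not the whole source for both genes at once, since 2 contrasts with no WT and no common library (bhlh151-KO minus bhlh58-KO, and bHLH151-OE minus bHLH58-OE) still correlated over genes at 0.603, and at 0.575 or more with any library left out (the other 2 pairings of these 4 lines gave 0.341 and -0.339). As the only source, WT would give each pair of lines a covariance no larger than the variance of the changes in bHLH58-OE (0.043 with 3 SE added to the SD); bHLH151 was at 0.1541 above the simulated value, which excludes this, and bHLH58 at 0.0388, which leaves it open, as does the 0.0344 of both overexpression lines. A preparation batch shared by both bHLH151 lines cannot be told apart from an effect of bHLH151, since the labels give no batch and at most 37104 IDs reached 1 FPKM in those libraries against at least 37383 in all others.

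The double knockout departed less from WT than bhlh151-KO did. The SD of its log2 fold changes over genes, corrected for sampling error, was 0.338 (jackknife SE 0.019) against 0.527 (SE 0.0083). A factor per library shifts all log2 values nearly alike and enters these SDs only through the pseudocount. TPM and median-of-ratios scaling apply such factors, so they cannot test scaling here. Quantile normalization, which changes the shape of the distributions, left the SDs at 0.333 for the double knockout and 0.513 for bhlh151-KO. A single aberrant library is argued against, since with any library left out the lowest value for bhlh151-KO (0.52) exceeded the highest for the double knockout (0.349). What stays open is the background of the line and a preparation batch. With 1 line per genotype, a change particular to line 40 of bhlh151-KO cannot be told apart from the effect of losing bHLH151. The labels give no batch, and 36450 to 36911 IDs reached 1 FPKM in the bhlh151-KO libraries, against at least 37383 in those of the double knockout. A suppressing effect of losing bHLH58 as well remains an untested hypothesis.

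More genes were lower than higher in both bHLH151 lines and the double knockout, though not among the genes of the double knockout with a mean of at least 5 FPKM (3956 higher, 3726 lower). The excess lay in changes under 2-fold. At 2-fold or more, 622 were higher and 188 lower in the double knockout, 552 and 271 in bHLH151-OE, and 1504 and 1540 in bhlh151-KO. In bhlh151-KO, a few abundant genes taking more of the FPKM total are argued against. The 100 most abundant IDs held 9.95% of that total there and 10.25% in WT (a difference of -0.3 points). FPKM is scaled by transcript length, so the share of fragments these IDs took is not known. Whether the scaling of the libraries accounts for the excess of lower calls stays open. Under median-of-ratios scaling 47.5% of the calls in bhlh151-KO were lower, against 63.6% as deposited, with 45% in bHLH151-OE and 42.7% in the double knockout. That scaling brings the median change near 0 by construction, and after rescaling to TPM the lower shares grew to 66.5% (bhlh151-KO), 68.7% (bHLH151-OE) and 64% (double knockout). Which scaling is right cannot be read from FPKM values.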

How the results depend on the processing

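The scaling alternatives for the overlaps and those for the SDs, slopes and correlations of log2 fold changes were chosen after the data had been seen; the other alternatives were planned. The counts of the 10 comparisons stayed within 1.5 times their value under a pseudocount of 0.1, no filter, TPM, median-of-ratios and quantile scaling, a fit of only the compared groups, limma without trend and robust estimation, and library weights. The same held for the 12 overlaps under both scalings run on them. A mean of at least 5 FPKM, which tests fewer genes, gave 11255 calls for bhlh151-KO, 7682 for the double knockout and 8114 for bHLH151-OE. A 2-fold threshold, which keeps part of the calls by construction, gave 508 calls for bhlh58-KO, 3044 for bhlh151-KO, 810 for the double knockout, 169 for bHLH58-OE and 823 for bHLH151-OE against WT. It gave 249 for the double against bhlh58-KO, 1095 for the double against bhlh151-KO, 229 for bHLH58-OE against bhlh58-KO, 611 for bHLH151-OE against bhlh151-KO and 2865 non-additive genes. The overlaps in the same and in opposite directions were then 302 and 0 (both single knockouts), 250 and 1 (bhlh58-KO with the double), 502 and 1 (bhlh151-KO with the double), 84 and 2 (bHLH58 lines), 683 and 4 (bHLH151 lines) and 56 and 5 (both overexpression lines). With 1 library left out, counts ran from 6953 to 7574 (bhlh58-KO), 17455 to 18117 (bhlh151-KO), 9147 to 10286 (double), 1338 to 1719 (bHLH58-OE) and 10723 to 11484 (bHLH151-OE), each against WT. They ran from 2353 to 3115 (double against bhlh58-KO), 8724 to 9365 (double against bhlh151-KO), 2371 to 3216 (bHLH58-OE against bhlh58-KO), 6710 to 7983 (bHLH151-OE against bhlh151-KO) and 10617 to 11426 (non-additive). Fewer libraries lower the power of each such fit, and every one gave fewer calls. The libraries that moved a count by over 1.5 times were WT replicate 1 (1338), WT replicate 3 (1403), bHLH58-OE replicate 1 (1423) and bHLH58-OE replicate 3 (1361) for bHLH58-OE against WT. They were bhlh58-KO replicate 2 (2431) and bhlh58/151-KO replicate 2 (2353) for the double against bhlh58-KO, and bhlh58-KO replicate 3 (2498) and bHLH58-OE replicate 3 (2371) for bHLH58-OE against bhlh58-KO.

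The libraries share replicate numbers 1 to 3 across groups, but the numbers do not pair them: deviations from the group means correlated over 0.1 in 0 of 45 same-number pairs (mean 0.0021), and 4 of 18 libraries correlated best with their own number. With the replicate block the counts were 9000, 19613, 11537, 2129 and 12829 for the 5 lines against WT in the order above, 3558, 10324, 3616 and 8329 for the other pairs, and 11825 for the non-additive genes.

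Of 656 alternative values for the 40 named results, 642 kept their direction and their call, 14 kept the direction and lost the call, and 0 reversed. The lost calls were those of PAxG03Gg0099500 (double against WT), PAxG03Gg0128300 (bhlh151-KO against WT) and PAxG06Gg0057900 (bHLH58-OE against bhlh58-KO, in the fit of only the compared groups). The gene lists and the targeted genes had no alternatives run, since the IDs carry no names, and no count-based test was run on FPKM. What depth limits cannot be stated, since depth is unknown.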

Other observations

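In this part the test of deviations within groups was set before its result was seen; the other tests, the sets of IDs and the 8-fold rule were chosen after the values had been seen.

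Against the common direction of the bHLH58 lines, 21 of the 76 IDs at least 2-fold lower in bHLH58-OE were called higher in bhlh58-KO. Their median log2 fold change was -1.60 in bHLH58-OE and 0.73 in bhlh58-KO. The same 21 IDs had a median of -0.92 in bHLH151-OE, where 20 were called lower and 1 higher, -0.48 in bhlh151-KO (14 lower, 1 higher) and -0.29 in the double knockout (10 lower, 1 higher). Their deviations from the group means also went together: the mean pairwise correlation over the 18 libraries was 0.372, while 1000 random sets matched on level averaged 0.0073 and reached at most 0.131, and the other 55 IDs 2-fold lower in bHLH58-OE gave 0.043. The set may thus be 1 co-regulated group rather than unrelated genes. Reads split between near-identical copies, a difference in harvest time and a shared regulator would each give such a correlation, and none of them was tested.

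The bhlh151-KO line had low values of 2 neighboring IDs that all other groups kept. Among IDs with at least 1 FPKM in every library of the other 5 groups, only PAxG05Ag0135100 and PAxG05Ag0135300 were more than 8-fold below all of those libraries there, at 0.184 ± 0.213 and 0.278 ± 0.196 FPKM against 36.6 ± 2.17 and 9.63 ± 0.928 in WT (n = 3). By the same rule 1 ID was lost in the double knockout (PAxG07Ag0058500, 0.060 ± 0.028 against 2.19 ± 0.638 in WT), 1 in bHLH58-OE (NewGene_4484, listed at 0 in its 3 libraries against 3.45 ± 0.163 in WT), and 1 was gained in bhlh58-KO, with at least 1 FPKM in each of its libraries (PAxG15Gg0124300, 2.96 ± 0.942, listed at 0 in all other libraries). WT and bHLH151-OE had 0 IDs that pass these limits. The 2 IDs are adjacent in the order of tested IDs, which was seen in the values and not tested. The next 2 tested IDs, PAxG05Ag0135400 and PAxG05Ag0135600, were also lower in bhlh151-KO (4.64 ± 0.402 and 4.8 ± 0.69 FPKM against 18.0 ± 1.92 and 16.4 ± 1.47), while PAxG05Ag0134900 on the other side was at 29.8 ± 0.870 against 29.0 ± 0.874. PAxG05Ag0135400 and PAxG05Ag0135600 were called lower in bHLH151-OE too (12.2 ± 0.750 and 8.79 ± 0.864 FPKM).

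Changed IDs stood next to each other more often than chance gives. Pairs of adjacent IDs that both changed at least 2-fold in one direction numbered 42 in bhlh58-KO, 312 in bhlh151-KO, 120 in the double knockout, 16 in bHLH58-OE and 58 in bHLH151-OE. Shuffling the IDs within their numbered sets 1000 times gave means of 3.07, 105.3, 9.86, 0.337 and 8.76, and at most 20 in the double knockout. The permutation p was 0.001 in each line, the smallest 1000 shuffles can give, and stayed 0.001 after adjustment over the 5 lines. Gain or loss of a whole numbered set is argued against, since the largest departure of any of the 38 set medians from the median of all was 0.045 on the log2 scale. Tandem copies that share regulation or reads may account for such pairs, and the IDs alone do not test this.

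The excess of lower over higher calls in bhlh151-KO against WT differed with level, under the deposited scaling, the only one tried for this. The genes with the lowest mean FPKM, up to 2.83, had 1290 higher and 3935 lower calls, those from 2.83 to 7.80 had 1742 and 4716, and those above had 4177 and 3968. In the double knockout the numbers were 819 and 1786, 1118 and 2466, and 3213 and 2412. All 5 transgenic lines shared 543 genes called higher and 384 called lower than WT. These are the 927 genes in which WT stood apart from every line, and all 5 comparisons share the same 3 WT libraries. The group that stood apart most often was bhlh151-KO, with 4467 genes called in 1 direction against each of the other 5 groups, next to 927 for WT, 280 for bhlh58-KO, 237 for bHLH151-OE and 233 for the double knockout, while bHLH58-OE had 27 higher and 88 lower.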
